A study of Mus musculus with 2 samples.

How the data were processed

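DNase-seq maps open chromatin: nuclei are treated with DNase I, which cuts DNA where it is not covered by nucleosomes or bound proteins, and the cut ends are sequenced. It was done on left cerebral cortex tissue from 2-month-old male mice of the strain B6CASTF1/J, the F1 hybrid of C57BL/6J and CAST/EiJ. There were 2 samples in 1 group, which the labels number as biological replicates 1 and 2 and describe as separate animals under a donor record shared by the strain. There was no second tissue, age, sex or treatment, so the comparisons made were between genes, regions and sequences within the tissue, and between the 2 libraries.

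For each replicate the authors deposited 2 peak lists, 1 list of footprints and 1 track of false discovery rates, all on mm10 per the file headers. The value used from each peak list was the peak height, a signal as the authors gave it, derived from the replicate's own filtered alignment per the labels' file notes. Every deposited height was a whole multiple of 1 step per replicate, 0.00432 in replicate 1 and 0.00675 in replicate 2, within a tolerance of 0.05 steps. How the heights were scaled is not given in the sources used here. The deposited FDR values, from the track of false discovery rates, list stretches of bases with an FDR under 0.05. In the deposited footprint lists the only value column held 1 constant, so footprints were used as positions without a score. The aligner, the peak caller, the footprint caller, their settings and any correction for the cutting preference of DNase I are not given in the sources used here. The files held no read counts, so the sequencing depth of each library is unknown, and no interval or detection limit that needs it is given. Intervals of shares over peaks or windows are exact Clopper-Pearson intervals and cover counting error over those items only, and neighbouring peaks and genes are not independent.

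The notes deposited with the files do not tell the 2 peak lists of a replicate apart. The choice fixed before the data were examined was then the list with the narrower median interval, but the medians of the deposited intervals were equal in replicate 1 and differed by 1 bp in replicate 2, so the shorter and stricter list was used. Every peak of the shorter lists held a base with an FDR under 0.001, against 61.1% of the longer list's peaks in replicate 1 and 63.6% in replicate 2. Peaks of a list that overlapped each other were joined and given the highest height, which removed 1089 intervals in replicate 1 and 522 in replicate 2. No peak lay outside chromosomes 1 to 19, X and Y. A region was shared where peaks of both replicates overlapped by 1 bp or more, and overlapping peaks of both were merged into 1 region.

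Sequence came from GRCm38.p6 and genes from GENCODE release M21, with 21938 protein-coding genes on chromosomes 1 to 19, X and Y. The peaks lay within the reference length on 21 of 21 chromosomes. A promoter was the 500 bp on both sides of any annotated transcription start site (TSS) of a gene. A gene's promoter was called accessible where each replicate had a peak at any of its TSSs, not necessarily the same TSS. The promoter height was that of the tallest such peak in each replicate. A distal region lay over 2000 bp from every annotated TSS. A locus was the gene body with 20 kb on both sides, so the loci of close neighbours overlap and their peaks count for both.

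There were 27 gene lists with 348 distinct genes, all of which were matched to the annotation: pan-neuronal, cortical excitatory neuron, cortical layer, inhibitory neuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, mural, fibroblast and meninges, choroid plexus and ependyma, blood cell, immediate early, glutamate receptor and postsynapse, voltage-gated ion channel, striatum, cerebellum and hindbrain, hypothalamic peptide and aminergic, Hox, liver, muscle and heart, germ cell, housekeeping, circadian clock, interferon response and imprinted. Promoter accessibility of a list was compared with all other protein-coding genes by a two-sided Fisher's exact test. The number of shared distal regions per locus was set against 10000 random lists of the same size matched on locus length in 20 bins, as a two-sided permutation p. Both families were adjusted over the 27 lists by the Benjamini-Hochberg method, and a list was called at an adjusted p under 0.05. As an alternative, promoters were compared with genes in the same 1 of 20 bins of CpG observed over expected, by permutation within bins.

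The difference between the libraries was the log2 ratio, replicate 2 over replicate 1, of the summed heights in a locus, over 17457 genes with a peak in the locus in both. The median over a list was placed among the medians of 10000 random lists matched on the mean of both sums, and not on locus length. With 1 library against 1 library no p-value was computed, and the percentile describes these libraries. A sum of heights moves with the number of peaks called, so the covered length and the mean height are given beside it.

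Motifs were 29 consensus sequences and 2 scrambled controls, matched without mismatch on either strand. The central 150 bp of each shared distal region were compared with 1 window lying 5 to 50 kb away. The window had the same size and GC content (2% bins). It lay outside all peaks of both lists and outside all stretches listed with an FDR in either replicate. The comparison was a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the motifs. For 872 of 23895 regions no such window existed. Footprints, widened by 5 bp on both sides, were compared by the same test where they lay inside peaks of the longer list. With a control window these were 224806 in replicate 1 and 213589 in replicate 2. The control windows had the same width and lay at random places of the same peaks outside footprints, without a GC match. Repeated sequence was recognised by counting how often each 25-mer of a region occurs in the genome, and a region with 50% or more of its 25-mers in more than 1 copy was passed over when the strongest regions were listed.

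The genes named follow a rule set with the other choices. They are the 2 members of each list with the highest mean summed height in the locus, up to 2 members without a promoter peak in either replicate, in alphabetical order, for lists called by the promoter or the distal test, the genes nearest to the 10 strongest unique distal regions, the 10 genes with most shared distal regions within 50 kb of a TSS, and the 5 genes with the largest log2 ratio in each direction among those above the median summed height. Not every gene the rule takes is named. Other genes are named as examples or where they make up a small count, and those were chosen after their values were seen.

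The tests of gene lists, the comparison of summed heights between the libraries and the motif test in distal regions were tested on simulated data built on the real genes or windows. The footprint comparison, the ratios over shared regions, the lists matched on promoter height and the X chromosome ratio were not. The promoter test called 40 of 40 planted lists and 0 of 40 unchanged lists, and the version within CpG bins called 9 of 10 planted and 0 of 10 unchanged lists, over 21938 genes. The planted lists were drawn from all genes. The 9 of 10 therefore does not carry over to CpG-rich lists, whose matched genes are mostly accessible already. The distal test called 10 of 10 planted and 0 of 10 unchanged lists, with a median ratio of 2.87 for lists made with 3. In the comparison of the libraries, over 17457 genes, 9 of 10 planted and 0 of 10 unchanged lists fell outside the central 95% of random lists on the planted side or on either side. Of 10 planted motifs 10 were called over 11510 windows, and the 2 of 21 other motifs also called occur inside planted ones. The alternatives tried were the longer peak lists, the stronger part of each list, other overlaps, promoter widths, flanks, backgrounds and window sizes, and each replicate on its own. A stricter footprint threshold could not be tried because the deposited footprints carry no score. The GC-adjusted ratios between the libraries, the mean ratio over shared regions without that adjustment, the longer list of replicate 2 for excitatory neuron promoters and the shorter lists for footprints were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.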

Results

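Open chromatin was mapped by DNase-seq in the left cerebral cortex of 2 adult male B6CASTF1/J mice, taken as biological replicates 1 and 2 of a single group. Cortex tissue holds excitatory and inhibitory neurons, astrocytes, oligodendrocytes and their precursors, microglia and vessel cells, so the peaks are a sum over these cells. Replicate 1 had 63928 peaks covering 13.3 Mb and replicate 2 had 76440 peaks covering 15.3 Mb, and the median width was the same in both. Peak heights, which are the authors' own values, had a median of 0.915 in replicate 1 and 0.689 in replicate 2 and reached 44.8 and 33.6. The sequencing depth behind them is unknown. The smallest step between heights was 1.56 times larger in replicate 2.

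The first comparison asked how far the 2 animals share their open chromatin. The tallest peaks of each animal were nearly all found in the other, and most of the lowest were not. Of the replicate 1 peaks, 70.7% overlapped a replicate 2 peak (95% interval 70.3% to 71.1%, exact), and of the replicate 2 peaks 59.3% overlapped a replicate 1 peak (59.0% to 59.7%). Random placement on the same chromosomes gave 1.23% and 1.03%. The share rose with height, from 32.5% in the lowest quintile of replicate 1 peaks to 98.4% in the highest, and from 21.1% to 98.0% in replicate 2. Of the 18730 replicate 1 peaks without a partner, 40.2% lay in the longer peak list of replicate 2, and of the 31084 replicate 2 peaks without a partner 40.1% lay in the longer list of replicate 1. Over 43811 peaks paired 1 to 1, heights correlated across peaks with a Spearman correlation of 0.796 and, on the log2 scale, a Pearson r of 0.856. Peaks are not independent replicates and no p-value was computed. The median log2 ratio of heights, replicate 2 over replicate 1, was -0.45.

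**Figure D1:**
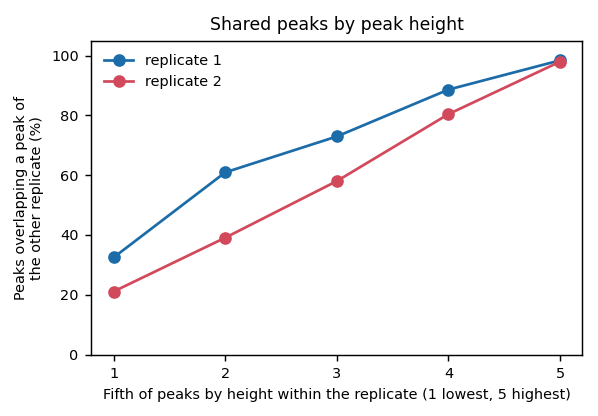
The vertical axis shows the percentage of peaks that overlap a peak of the other replicate, and the horizontal axis shows quintiles of peak height within each replicate, with 1 line per replicate. The share goes up from 32.5% to 98.4% in replicate 1 and from 21.1% to 98.0% in replicate 2.

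Merging gave 44745 shared regions. Promoters made up 37.2% of them (36.8% to 37.7%), which was 11.4 times their share of the genome, introns 28.8%, intergenic sequence 28.7% and other exons 5.37%. Promoter regions were the taller ones, with a median height of 1.92 (geometric mean of both replicates) against 0.873 elsewhere. The highest quintile of shared regions was 84.6% promoters and the lowest 17.0%. The peaks found in 1 library alone differed in place: 31.2% of those of replicate 1 and 8.44% of those of replicate 2 lay at promoters. Distal regions, over 2000 bp from any TSS, numbered 23895, or 53.4% of the shared regions.

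The X chromosome, present in a single copy in male mice, had 6.95 shared regions per Mb, 0.375 of the autosome median of 18.5 per Mb. The autosomes ranged from 14.2 per Mb on chromosome 3 to 27.0 per Mb on the gene-rich chromosome 11. Within the replicates the X ratio was 0.387 and 0.397. Shared regions on the X were also lower, with a median replicate 1 height 0.697 times that of the autosomes. Over each replicate's own peaks the height ratio was 0.664 in replicate 1 and 0.621 in replicate 2. The Y chromosome held 21 shared regions.

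The strongest distal regions that are unique in the genome lay near genes of several kinds. The strongest of all was a 420 bp region at chromosome 15, 99735641 to 99736060 (mm10), in an exon of the annotation 10.2 kb from the TSS of Cox14, an assembly factor of respiratory complex IV, with heights of 26.7 and 18.1. It held a NEUROD-type E-box and a PU.1 motif. The next was at chromosome 13, 58177581 to 58177820, in an exon 3.92 kb from a TSS and inside Ubqln1, which encodes a ubiquitin-binding protein, with heights of 14.6 and 13.8. Others lay 53.4 kb from Cstad, 4.78 kb from Map1lc3b, an autophagy gene, 52.2 kb from Wnt7b, which encodes a Wnt ligand, 39.2 kb from Ptma, 6.44 kb from Trappc9, 72.6 kb from Irf2bp2, within C87436 and within an intron of Prdm2, a histone methyltransferase gene. Of the 10 regions, 4 were in exons, 2 in introns and 4 intergenic, and 0 held a CTCF motif. To reach them 9 stronger or similar places were passed over, because at least 50% of their 25-mers occur in more than 1 copy.

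Among the 10 genes with most distal regions, Kalrn, whose product acts in dendritic spines, had 20 shared distal regions within 50 kb of its TSSs, Shank2, a postsynaptic scaffold gene, had 19, and Dlgap4, which encodes a scaffold partner of PSD-95, had 16. Kcnma1, the BK potassium channel gene, and Cmip had 15 each. Trim27 and Prkag2, a regulatory subunit gene of AMP-activated kinase, had 14 each. Mid1, a ubiquitin ligase gene that crosses the pseudoautosomal boundary of the C57BL/6J X chromosome, had 20 and its neighbour Gm21887 had 18. The strongest region there consists wholly of sequence in several copies, with a median of 4 copies per 25-mer, so the counts for Mid1 and Gm21887 are uncertain. As a list, glutamate receptor and postsynaptic genes had a mean of 3.80 shared distal regions per locus against 3.69 in length-matched random lists and were not called (adjusted p 0.933 by permutation).

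The second comparison asked which promoters were open, by gene lists that stand for cell types and functions. Immediate early genes, which neurons transcribe within minutes of activity, had an accessible promoter in 18 of 18 cases, circadian clock genes in 12 of 12, housekeeping genes in 14 of 14, glutamate receptor and postsynaptic genes in 14 of 15, pan-neuronal genes in 13 of 14 and cortical layer genes in 11 of 12. Over all 21938 protein-coding genes 12324, or 56.2%, were accessible in both replicates. Promoters of several lists of cell types that are rare in cortex, or of other tissues, mostly had no peak called in both replicates. Of the Hox genes 0 of 16 were accessible, of the muscle and heart genes 0 of 14 and of the liver genes 1 of 14. Of the mural genes it was 0 of 10 and of the endothelial genes 2 of 13. The peaks are a sum over all cells, so a missing peak does not show that a promoter is closed in a rare cell type.

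The 6 lists called higher had adjusted p values of 3.543e-04 for immediate early, 0.00222 for housekeeping, 0.00609 for circadian clock, 0.00909 for glutamate receptor, 0.0120 for pan-neuronal and 0.0262 for cortical layer genes (two-sided Fisher's exact tests). Against genes of the same CpG content 0 of the 6 were called, with adjusted p values from 0.170 for pan-neuronal to 0.990 for cortical layer genes. Immediate early, housekeeping and clock genes were already all accessible, against 87.3%, 86.2% and 85.4% of genes in the same CpG bins. For them no outcome could have been called higher, so the missing call decides nothing. Cortical layer genes, set against 83.3% in their CpG bins, also left little room for a higher call. Their missing call does not show that CpG content accounts for the difference. Among immediate early genes the promoter of Junb, an AP-1 subunit gene (ENSMUSG00000052837.6, chromosome 8, 84974484 to 84978718), had peaks of height 5.47 in replicate 1 and 3.61 in replicate 2, and that of Fosb, another AP-1 subunit gene, 5.13 and 3.38. Of the clock genes, Per1, a repressor in the clock's feedback loop (ENSMUSG00000020893.17, chromosome 11, 69095217 to 69109960), had 10.1 and 10.6, and Nr1d1, which encodes the nuclear receptor REV-ERB alpha, 10.5 and 7.01.

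Among neuronal genes, Dlg4, which encodes the postsynaptic scaffold PSD-95, had promoter heights of 2.86 and 2.24, and Rbfox3, the gene of the neuronal antigen NeuN, had a peak of 1.34 in replicate 1 and none in replicate 2. It was the pan-neuronal gene not counted as accessible, but with the longer peak lists all 14 were accessible in both replicates. Of the cortical layer genes, Tle4, a corepressor gene of deep layers, had the tallest promoter peak of its list at 13.5 and 10.9, and Cux1, of upper layers, had 2.21 and 0.918. Fezf2, a selector of deep-layer projection neurons, had a promoter peak in replicate 1 alone. Shank2 had promoter heights of 2.59 and 2.82, while Shank1 had no promoter peak in either replicate in the shorter lists. With the longer lists all 15 glutamate receptor and postsynaptic genes, Shank1 among them, were accessible in both.

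The lists called lower covered 12 cell types or tissues. Against genes of the same CpG content 8 of the 12 lost their call: microglial and blood cell genes (adjusted p 1 for both), liver (0.672), endothelial (0.119), choroid plexus (0.0924), fibroblast and hypothalamic (0.0844 for both) and muscle and heart genes (0.0713). The shares were close for microglial (20% against 20.9% in the same CpG bins) and blood cell genes (8.33% against 11.1%). They stayed further apart for endothelial (15.4% against 39.6%), choroid plexus (10% against 35.6%) and fibroblast genes (20% against 48.8%). The same held for hypothalamic (15.4% against 41.6%), muscle and heart (0% against 26.3%) and liver genes (7.14% against 17.1%). For blood cell, liver and microglial genes few matched genes were accessible, so lists of this size left little room for a lower call. Their missing call therefore does not show that CpG content accounts for the difference. Microglial genes were accessible in 3 of 15 cases (adjusted p 0.0127), with a promoter peak at Aif1, which encodes the microglial protein IBA1 (0.993 and 0.763), and none at the chemokine receptor gene Cx3cr1 or the complement genes C1qa and C1qb. Of the 13 endothelial genes (adjusted p 0.00921) the glucose transporter gene Slc2a1 had peaks of 3.70 and 1.69, and Cdh5, Cldn5 and Erg, for VE-cadherin, a tight junction protein and an ETS factor, had none at their promoters. Mural genes (0.00141) included Des, with a promoter peak in replicate 1 alone, and Vtn, Abcc9 and Acta2, with none. Fibroblast and meninges genes were accessible in 2 of 10 cases (0.0390): the collagen gene Col1a1 (2.09 and 1.37) and the forkhead gene Foxc1 (1.20 and 0.851), but not Col1a2 or Col3a1. Choroid plexus and ependyma genes were accessible in 1 of 10 (0.0127). That gene was Foxj1, a regulator of ciliated cells, while Ccdc153 had a peak in replicate 1 alone and Clic6 and the water channel gene Aqp1 had none. Blood cell genes were accessible in 1 of 12 (0.00316), with no promoter peak at the erythroid factor gene Klf1 or at Alas2 of haem synthesis. In replicate 1 alone 4 of 13 endothelial genes and 3 of 10 genes each of the mural, fibroblast and choroid plexus lists had a promoter peak, and these 4 lists were not called (adjusted p 0.0651 for endothelial genes and 0.0700 for the others). Fibroblast genes were also not called with the longer peak lists (0.0673) or with the stronger part of each list (0.0907), nor cortical layer and germ cell genes with the stronger part (both 0.0578).

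Genes of the cerebellum and hindbrain, of the hypothalamus and of organs outside the brain also mostly had no accessible promoter. Of the cerebellum and hindbrain genes 1 of 10 was accessible (adjusted p 0.0127), Cbln3, a granule cell gene, with 2.08 and 0.945, while the Purkinje cell gene Pcp2 and the transcription factor genes Atoh1 and Barhl1 had no promoter peak. Hypothalamic and aminergic genes were accessible in 2 of 13 (0.00921), a call that was lost with 2000 bp on both sides of a TSS (5 of 13, 0.201). Agrp, for a feeding peptide, had a promoter peak in replicate 1 alone, and Hcrt, Avp and the serotonergic factor gene Fev had none. The Hox genes (4.962e-05) included Hoxa10 and Hoxd9, the muscle genes (1.294e-04) Tnni3, Acta1 and Actc1, and the germ cell genes, accessible in 2 of 11 (0.0233), Zp3, Prm1, Acrv1 and Ddx4, all without a promoter peak. Of the liver genes (0.00123) Apoh was accessible, with 0.751 and 2.44, and Alb, Ahsg and Apoa2 were not. The tallest peaks in the loci of Klf1 and Pcp2 were not their own, and lay 76 and 77 bp from TSSs of the neighbouring genes Gcdh and Pet100.

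The remaining 9 lists were not called. Astrocyte genes were accessible in 10 of 14 cases, among them Aldh1l1 (0.630 and 0.520) and the bicarbonate transporter gene Slc4a4 (1.01 and 1.42). Oligodendrocyte genes were accessible in 7 of 14, with Mbp, for myelin basic protein, at 1.98 and 1.09 and the myelin regulator gene Myrf at 1.58 and 0.540. Oligodendrocyte precursor genes were accessible in 6 of 10, with Sox6 at 1.41 and 1.20 and no promoter peak at Matn4. Inhibitory neuron genes were accessible in 9 of 16: Pvalb, a marker of fast-spiking interneurons, had 1.10 and 0.581, and Slc32a1, the vesicular GABA transporter gene, had 1.47 in replicate 1 and no peak in replicate 2. Voltage-gated ion channel genes were accessible in 11 of 13, with the calcium channel genes Cacna1c at 1.71 and 0.662 and Cacna1e at 1.17 and 0.810. In replicate 1 alone all 13 had a promoter peak and the list was called higher (adjusted p 0.00811). Striatum genes were accessible in 8 of 11, imprinted genes in 12 of 15 and interferon response genes in 3 of 11. Among these Ppp1r1b, for DARPP-32, had 2.21 and 1.30, Rarb, a retinoic acid receptor gene, 1.72 and 1.22, Peg3 2.83 and 2.73, and Impact 2.68 and 2.07, while Rsad2, an interferon response gene, had a peak in replicate 1 alone. With the longer peak lists astrocyte genes (13 of 14, adjusted p 0.0217), striatum genes (11 of 11, 0.0165) and ion channel genes (12 of 13, 0.0320) were called higher and interferon response genes lower (3 of 11, 0.0416). With 2000 bp on both sides of a TSS ion channel (0.0322) and imprinted genes (13 of 15, 0.0485) were called higher and interferon response genes lower (0.0485), as these were with the stronger part of each list (1 of 11, 0.0136).

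Cortical excitatory neuron genes differed most between the libraries in the share with a promoter peak. Their promoters were accessible in 4 of 12 cases (adjusted p 0.180), but all 12 had a peak in replicate 1, where the list was called higher on its own (adjusted p 0.0102). With the longer peak lists 10 of 12 were accessible, or 83.3% against 60.97% of other genes (adjusted p 0.155), and with 2000 bp on both sides of a TSS 7 of 12, or 58.3% against 59.8% (adjusted p 1). Camk2a, a kinase gene of excitatory synapses, had 3.61 and 2.72, Mef2c 2.10 and 1.14, Emx1 1.09 and 0.760, and Neurod6 0.747 and 1.23. The vesicular glutamate transporter gene Slc17a7 had 1.21 in replicate 1 and no promoter peak in replicate 2, and the same held for Tbr1, Neurod1, Neurod2, Sv2b, Camkv and Nptx1, among others. Genes of this list other than Camk2a and Slc17a7 were chosen after their values were seen.

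Promoter accessibility followed CpG content, from 0.273% of genes in the lowest of 20 bins of CpG observed over expected to 94.3% in the highest. Against genes of the same CpG bins 0 lists were called higher and 4 stayed lower: Hox (adjusted p 0.00270), cerebellum and hindbrain (0.00270), mural (0.0126) and germ cell genes (0.0256), by permutation within bins. Immediate early, housekeeping and clock genes could not be called higher there even with all of their promoters accessible. Of the 16 Hox genes 0 were accessible, against 81.3% of genes in the same CpG bins. The Hox list holds neighbouring genes, and neither these permutations nor Fisher's exact test allowed for that. Its p values are therefore less certain. A shared region with heights of 2.21 and 0.831 lay 53 bp from a TSS of Hoxa7, a Hox gene not on the list.

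**Figure D2:**
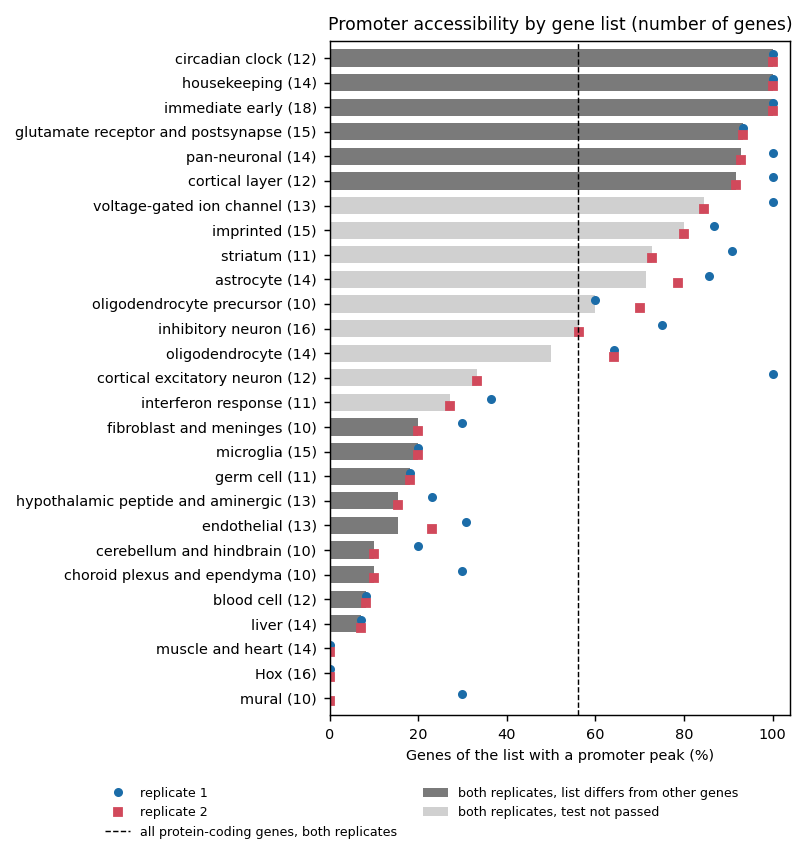
Bars show the percentage of each list's genes with a promoter peak in both replicates, points show each replicate alone, and the dashed line marks the 56.2% of all protein-coding genes. Dark bars are lists whose share differs from other genes by Fisher's exact test. The largest gap between the replicates is that of the cortical excitatory neuron list.

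The third comparison asked which lists have more distal regions than loci of their length. Oligodendrocyte, immediate early and circadian clock genes did. Oligodendrocyte loci held a mean of 2.14 shared distal regions against 0.796 in length-matched random lists, a ratio of 2.69, with at least 1 region in 10 of 14 loci. Mbp had 9 and Myrf 2, and Opalin, for a myelin protein, had 3 although it had no promoter peak. Immediate early loci held 1.78 against 0.652, a ratio of 2.73, in 12 of 18 loci, with 5 at Fosb and 6 at Egr1, a zinc finger factor gene. Clock gene loci held 2.25 against 0.894, a ratio of 2.52, in 8 of 12 loci, with 8 at Nr1d1 and 6 at Arntl. Each had an adjusted p of 0.0144 by permutation. The other 24 lists were not called. Ion channel loci had the next highest percentile among the random lists (mean 4.38 against 2.63, adjusted p 0.406), with 9 at Cacna1c and 12 at Cacna1e. Germ cell loci had 0.273 against 0.873 (adjusted p 0.406). The calls depended on the flanks. With the gene body alone 0 of the 3 were called: the ratio was 2.52 for oligodendrocyte genes (adjusted p 0.594), 2.77 for clock genes (0.346) and 0.879 for immediate early genes (1). With flanks of 100 kb the clock genes were not called (ratio 1.73, adjusted p 0.0792). Without replicate 2 the clock genes alone were called (ratio 3.49). Oligodendrocyte and immediate early genes then had ratios of 2.14 and 2.22 (adjusted p 0.239 for both by permutation). Without replicate 1 the oligodendrocyte (2.17) and immediate early genes (2.56) were called, and the clock genes were not (1.78, adjusted p 0.198).

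The fourth comparison asked which transcription factor motifs mark the distal regions. The motif of CTCF, the factor that anchors chromatin loops, was found in 2855 of 23023 regions, or 12.4%, against 15 of the same number of GC-matched windows, a ratio of 190.3. The motif of AP-1, the dimer of Fos and Jun proteins induced by neuronal activity, was found in 2306 regions against 572 windows (ratio 4.03, 95% interval 3.69 to 4.41, adjusted p 4.728e-259). The NEUROD-type E-box, bound by basic helix-loop-helix factors of neurons, was found in 9.62% against 3.96% (ratio 2.43, 2.25 to 2.62). The activity-regulated factors MEF2 (ratio 7.65, 4.96 to 11.8) and EGR (5.71, 3.41 to 9.55) and the cilium and neuron factor RFX (23.5, 10.4 to 53.2) also had more. Without the GC match the ratios were 2.44 for MEF2, 9.77 for EGR and 289.8 for CTCF, and EGR had 2.71 over the whole peak and 13.7 in the central 50 bp. Without replicate 2 EGR had 3.36 and RFX 57.3, and without replicate 1 CTCF had 98.6. The control windows were not matched on CpG frequency or repeated sequence, so a part of either in the motif ratios is not excluded.

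In all 16 motifs were called more frequent and 4 less frequent. The others called more frequent were NRF1 (7.40), NFI (4.75), CRE (4.36), the LHX2/6 motif (2.17), the POU octamer (1.90), the homeobox motif (1.89), the CACGTG E-box (1.52), FOX (1.18), TEAD (1.14) and the scrambled control of AP-1 (1.25, adjusted p 1.909e-05). Since that control was itself called, ratios of the size of FOX and TEAD were no larger than that of a scrambled sequence. The scrambled control of CTCF was found in 12 regions and 10 windows and was not called. Less frequent were the motifs of SOX (0.880, adjusted p 0.00373), HNF4, a liver factor (0.583, 0.0229), GATA, a factor family of blood and endothelium (0.552, 2.538e-12), and NR4A (0.382, 7.591e-12). The microglial PU.1 motif was found in 1.15% against 1.36% (adjusted p 0.0718), and the liver HNF1 motif in 0 regions and 0 windows. Without the GC match the homeobox motif (0.668, adjusted p 5.688e-17) and FOX (0.829, 0.00983) were called less frequent, as was ROR (0.608, 9.658e-04). SP/KLF (3.59, 6.375e-24, against 0.995 with the match), ETS (57 regions against 19 windows, 3.236e-05), NFY (1.39, 0.00432), YY1 (6 regions against 0 windows, 0.0440) and PU.1 (1.25, 0.0243) were then called more frequent, while the POU octamer (1.12, 0.293), LHX2/6 (1.25, 0.379), TEAD (1.12, 0.0692) and HNF4 (1.03, 1) were not called. In the central 50 bp LHX2/6 (adjusted p 0.1505), NFI (0.0570), SOX (0.239), HNF4 (0.548) and the scrambled AP-1 control (0.0628) were not called and NFY was called more frequent (1.60, 0.0305), and over the whole peak FOX (0.252), SOX (0.0587) and HNF4 (0.0694) were not called. FOX was called less frequent without replicate 1 (0.883, 0.0162). The CRE ratio was between 2.17, without replicate 1, and 7.25, in the central 50 bp, where NRF1 had 15, and NFI also had 15 without replicate 2.

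**Figure D3:**
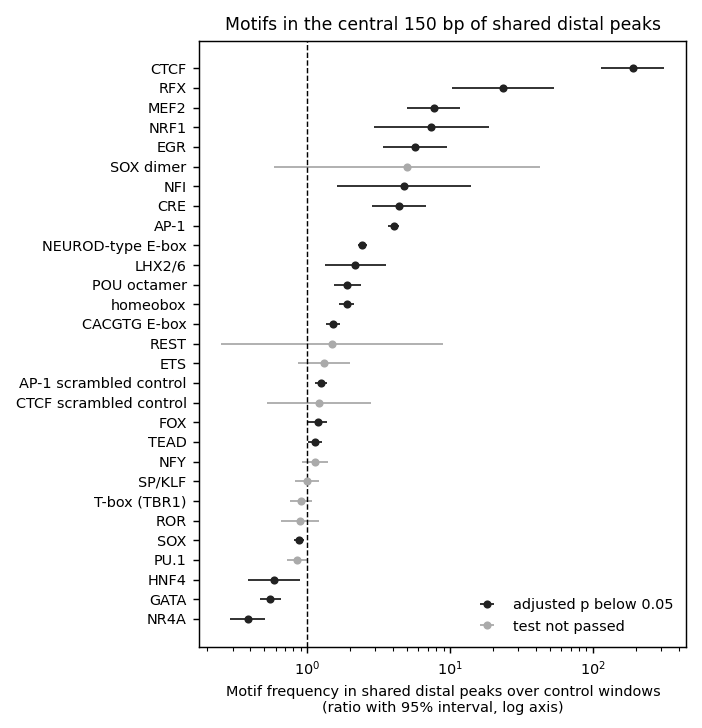
Points give the frequency of each motif in the central 150 bp of shared distal regions divided by its frequency in GC-matched control windows, on a log axis with 95% intervals. Black points passed the test and grey points did not. CTCF has the highest ratio at 190.3 and AP-1 has 4.03.

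Footprints are short stretches inside a peak that are protected from cutting, as by a bound protein. The authors listed 280338 in replicate 1 and 245020 in replicate 2, with median widths of 10 and 9 bp. Footprints with CTCF motifs were the most enriched in both libraries: 4155 footprints against 15 control windows in replicate 1 and 3603 against 61 in replicate 2, ratios of 277.0 and 59.1. The motif of NRF1, a regulator of mitochondrial genes, had ratios of 42.4 and 52.2, NFI, a factor family of glia and maturing neurons, 28.5 and 28.0, RFX 24.1 and 23.2, and EGR 14.4 and 10.3. CRE, the site of CREB, had 12.3 and 17.1, SP/KLF 12.1 and 8.45, the NEUROD-type E-box 2.56 and 3.14, and AP-1 1.57 and 2.43. In replicate 1 13 motifs were called more frequent and 9 less frequent, and in replicate 2 14 and 5. The scrambled control of AP-1 was among the less frequent in both (0.587, adjusted p 1.634e-20, and 0.717, 7.871e-10). The control windows were not matched on GC content, so a part of base composition in these ratios is not excluded. MEF2 was called in replicate 2 alone (1.80, adjusted p 8.963e-07; replicate 1 0.758, adjusted p 0.203), and T-box, the site of TBR1, was called less frequent in replicate 1 (0.755, 0.0110) and more frequent in replicate 2 (1.33, 0.00595). These differences between the libraries were not tested, and the T-box ratio of replicate 1 was closer to 1 than that of the scrambled control. The replicate 2 calls of both motifs were lost with footprints found in both replicates (MEF2 1.38, adjusted p 0.407, and T-box 0.953, 0.917) and with footprints without flanks (1.65, 0.182, and 1.05, 0.961), and the replicate 1 call of T-box was lost with the former (0.769, 0.208). With footprints in the shorter peak lists T-box was called in neither replicate (0.791, adjusted p 0.164, and 1.18, 0.186), while the MEF2 call of replicate 2 held (1.99, 1.243e-06). Several of the largest ratios also moved, that of NRF1 in replicate 1 to 342.0 and that of CTCF in replicate 2 to 365.6 without flanks and 142.6 in the shorter list.

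The exact positions of footprints were shared less often than those of peaks. Of the footprints, 64.7% in replicate 1 and 72.9% in replicate 2 overlapped peaks of the shorter lists, and 88.1% and 92.0% peaks of the longer lists, in which the motifs were compared. A footprint of the other replicate was overlapped by 35.6% (35.4% to 35.8%) and 42.5% (42.3% to 42.7%). Inside shared regions the shares were 52.5% and 62.8%, against 34.0% and 39.0% for footprints moved to random places of the same region.

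The fifth comparison set the 2 libraries against each other by gene list, as would show a different mix of cells. Summed heights in loci of glutamate receptor and postsynaptic genes were higher in replicate 2 relative to other genes, by 0.81 on the log2 scale, as were those of ion channel genes, by 0.46, and muscle and heart genes, by 0.47, and those of Hox genes were lower, with -0.44. Over shared regions alone these values were 0.37, 0.36, 0.23 and -0.46, and with adjustment for GC content 0.18, 0.15, 0.08 and -0.67. The values of summed heights are relative to the median of all genes, -0.58, and by them these 4 lists lay outside the central 95% of random lists. The glutamate receptor median of summed heights lay at the top of the 10000 random lists, and the percentiles of the others were 99.99, 98.2 and 0.98. These random lists were matched on summed height and not on locus length. Distal peaks per locus were also set against length-matched lists in each replicate alone. From replicate 1 to replicate 2 that ratio did not rise for glutamate receptor (1.34 and 1.25) and ion channel genes (1.53 and 1.498). It rose for muscle (0.453 and 1.48) and Hox genes (0.387 and 0.826). A part of locus length in the glutamate receptor and ion channel values is therefore not excluded. Among the members with peaks in both, Grin2a and Nlgn1, for an NMDA receptor subunit and a synaptic adhesion protein, had log2 ratios of 0.69 and 0.86, Shank2 0.03, Cacna1e 0.44 and Cacna1c -0.01, and Hoxa10 and Hoxd9 -1.08 and -1.01. The highest values of the muscle list were those of the neighbouring myosin genes Myh1, Myh2 and Myh4, with 2.95, 2.14 and 2.46. In the glutamate receptor loci the median covered length was 2018 bp in replicate 1 and 2591 bp in replicate 2, with mean heights of 0.986 and 0.853, against 855 and 840.0 bp and mean heights of 1.92 and 1.25 over all genes. In the ion channel loci it was 2338 and 2293 bp with 1.25 and 0.990, in the muscle loci 607 and 763 bp with 1.02 and 0.812, and in the Hox loci 315 and 341 bp with 1.05 and 0.638.

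Single genes were ranked among those above the median summed height. The largest differences towards replicate 2 were those of Ano3, of the anoctamin membrane proteins (2.61), Cdh12, a cadherin gene (2.26), Ipcef1 (2.03), L3mbtl4 (2.03) and Oprm1, the mu opioid receptor gene (1.90), the last of which overlaps Ipcef1 on chromosome 10. The largest towards replicate 1 were those of Cxxc5, for a CpG-binding protein (-3.31), Lrrc23 (-3.18), the muscarinic receptor gene Chrm4 and its neighbour Mdk (both -3.09) and Bcor, a corepressor gene (-2.84). These differences lay mainly in how many peaks were called and not in their height. Ano3 had 2 peaks covering 407 bp in replicate 1 and 17 covering 2875 bp in replicate 2, with mean heights of 0.779 and 0.561, and Cdh12 had 4 and 19 peaks covering 373 and 3019 bp, with 0.465 and 0.469. Cxxc5 had 24 peaks covering 5972 bp in replicate 1 and 2 covering 429 bp in replicate 2, with mean heights of 1.08 and 1.30, and Bcor had 24 and 3 peaks, with mean heights of 0.746 and 0.835.

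The libraries also differed by base composition. Shared regions under 35% GC had a median log2 height ratio of 0.12 and those of 80% GC or more -1.24. Of the replicate 2 peaks, 5.64% of those under 35% GC and 95.8% of those of 80% or more overlapped a replicate 1 peak. The median GC content was 56% in peaks of replicate 1 alone and 45.3% in peaks of replicate 2 alone. With ratios taken over shared regions and adjusted for GC content, an alternative added after the data were seen, 3 lists lay above the central 95% of random lists, cortical excitatory neuron (percentile 98.9), choroid plexus (98.3) and glutamate receptor genes (97.8), and 2 below, Hox (0) and imprinted genes (1.69). Ion channel and muscle genes no longer did, and with the number of peaks in place of heights 0 lists did. These are single libraries, so the differences have no replicate check. Neither these random lists nor those of the summed heights were matched on the closeness of genes. Percentiles of lists with neighbouring members that share regions, such as Hox and muscle genes, are therefore less certain.

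**Figure D4:**
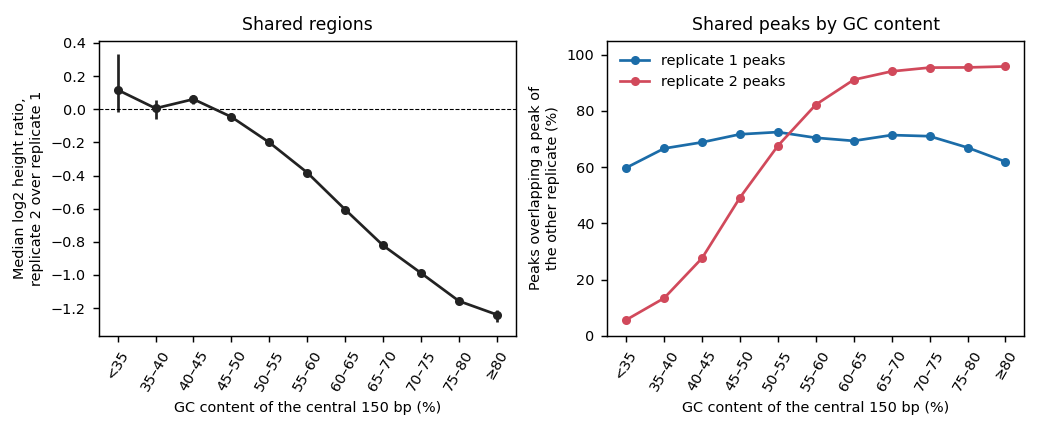
The left panel shows the median log2 height ratio of shared regions, replicate 2 over replicate 1, by GC content of the central 150 bp, with 95% bootstrap intervals. The right panel shows the percentage of each replicate's peaks that overlap the other replicate's, which for replicate 2 goes from 5.64% to 95.8% with GC content.

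Motifs also parted the libraries. In distal regions shared by both and compared at the same GC content, regions with a CTCF motif had a log2 height ratio lower by -0.63 than regions without (interval -0.65 to -0.62), and those with an AP-1 motif had a ratio higher by 0.46 (0.44 to 0.49). MEF2 regions differed by 0.44 (0.32 to 0.54), T-box regions by 0.26, NEUROD-type E-box regions by 0.20 and NR4A regions by -0.35 (-0.46 to -0.28). The scrambled AP-1 control differed by -0.04 (-0.08 to 0.03). In distal peaks found in 1 library alone, AP-1 motifs were in 4.16% for replicate 1 and 16.3% for replicate 2, and CTCF motifs in 6.85% and 1.58%. These comparisons were chosen after the data were seen.

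**Figure D5:**
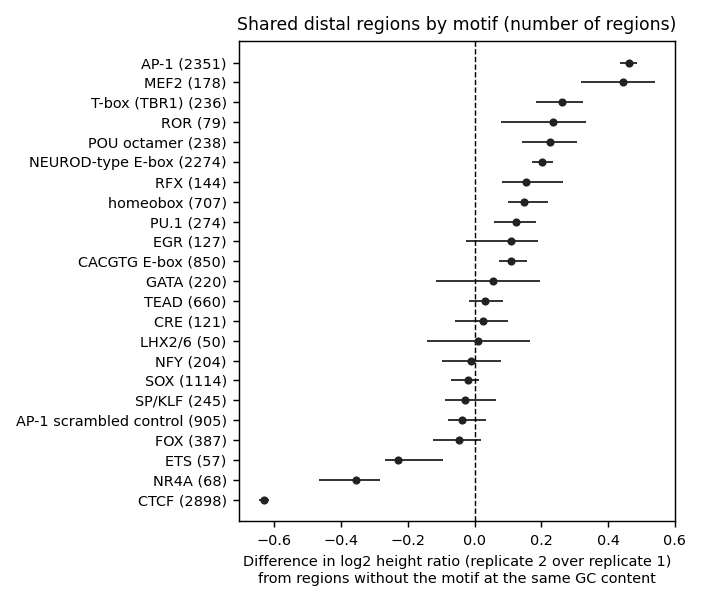
Points show, for shared distal regions with each motif, the difference in log2 height ratio (replicate 2 over replicate 1) from regions without the motif at the same GC content, with 95% bootstrap intervals and the number of regions in brackets. CTCF lies lowest at -0.63 and AP-1 highest at 0.46.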

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

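The tests of excitatory neuron promoters matched on height alone and with the longer list of replicate 2 were chosen after the result was seen, the former in place of an earlier test on the strongest promoters. That earlier test could not decide anything, since 0 of the 2701 strongest replicate 1 promoters lacked a peak in replicate 2. The other tests below were written down before they were run, but after the patterns themselves had been seen in the same data. The design has 1 group, so no biological explanation was tested by a contrast of groups.

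The deposited tracks of false discovery rates hold signal outside the peaks that was not compared. It served only to keep the control windows of the motif test in distal regions clear of it. Of the bases listed with an FDR, 36.0% in replicate 1 and 31.9% in replicate 2 lay outside every peak of both lists.

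Promoters of cortical excitatory neuron genes, a list singled out of 27 after the values were seen, had peaks at all 12 genes in replicate 1 and at 4 of these in replicate 2, but at 10 of them in the longer list of replicate 2. There the list did not stand apart, at percentiles 20.5 and 13.9 of random lists matched on GC content and height (mean 10.9) and on height (mean 11.1), so the pattern holds for the shorter list. In the shorter list a bias of replicate 2 against GC-rich promoters does not account for all of it: random lists matched on GC content and height of the replicate 1 peak kept a mean of 9.0 promoters (central 95% 6 to 11), and the list lay at percentile 0.02. A lower depth of replicate 2 alone does not either, since there lists matched on height kept a mean of 9.35 (7 to 12), with the list at percentile 0.01. Fewer excitatory neurons in replicate 2 may contribute and stay open, because the 20 distal shared regions in the list's loci had a median GC-adjusted log2 ratio of 0.17 with an interval from -0.28 to 0.44, and over regions called in both replicates the GC-adjusted percentile of 98.9 pointed the other way.

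AP-1 motifs were in 16.3% of distal peaks found in replicate 2 alone and in 4.16% of those found in replicate 1 alone. GC content and peak height do not account for this, since the odds ratio within bins of both was 4.20 (95% interval 3.73 to 4.74). The difference was not confined to which peaks passed the authors' threshold. Shared distal regions with the motif had a log2 height ratio higher by 0.46 (0.44 to 0.49) at the same GC content, while CTCF regions differed by -0.63. These regions were not matched on height, and each had passed the thresholds of both replicates. An effect of the thresholds on their ratios is therefore not excluded. A candidate explanation is a different state of activity in the 2 animals, and another is a different strength of DNase digestion, which could change sites of some factors more than others. Neither was tested, and no label records them. Immediate early genes as a list gave mixed values between the libraries. Their percentile among random lists was 12.95 by summed heights and 2.565 by number of peaks. It was 98.1 by promoter height and 97.4 over shared regions with GC adjustment.

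Peaks on the X chromosome were fewer and lower than on the autosomes. A lack of CpG-rich promoters on the X, 19.5% of genes against 41.3% on the autosomes, is not the whole cause: at CpG-rich promoters the median height on the X was 0.546 (0.490 to 0.615) of that of autosomal genes in the same CpG bins in replicate 1 and 0.622 (0.520 to 0.743) in replicate 2. The same ratios are consistent with the single X copy of male animals, which was set to give a ratio under 0.75.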

How the results depend on the processing

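The alternatives for the comparison of libraries that use shared regions, the longer list of replicate 2 for excitatory neuron promoters and the shorter lists for footprints were chosen after the data were seen, and all others before. No paired analysis was possible because there is 1 group. A stricter footprint threshold was not run because the deposited footprints carry no score, and the unknown depth limits what an absent peak means. The cause of the changes below was not tested unless named.

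Peak numbers were 108421 and 127162 with the longer lists and 32031 and 38292 with the stronger part of each list, by construction. Overlap was 68.8% and 58.8% with the longer lists, 79.4% and 66.4% with the stronger part, 67.1% and 66.97% with equal numbers and 58.0% and 48.5% with reciprocal overlap of 50%, which also gave a Spearman correlation of 0.822. The promoter share was 46.6% with 2000 bp on both sides of a TSS, 28.6% with the longer lists, and 25.4% to 35.3% without replicate 1 or 2. The X to autosome ratio of shared regions was 0.365 with the longer lists, which gave 0.408 and 0.430 in the replicates alone.

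Within CpG bins 0 promoter lists were called higher and 4 lower, and all 4 were among the lists called against all genes. Lists with every promoter accessible could not be called higher within the bins. Lists whose matched genes mostly had no accessible promoter left little room for a lower call. Under the other alternatives 5 to 9 were called higher and 8 to 12 lower. The excitatory neuron difference ranged from -23.8 to 38.5 percentage points without replicate 1 or 2. Of the 3 distal calls, 0 held with the gene body alone, where the immediate early difference was -0.0229 regions per locus and the ratios of the oligodendrocyte and clock genes were 2.52 and 2.77, 2 with the wider flanks, 3 with the longer lists and 1 to 2 without a replicate.

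Called more frequent in distal regions were 14 to 17 motifs under every alternative. Less frequent were 2 in the central 50 bp, 2 over the whole peak, and 4 to 6 otherwise. Without the GC match the differences in percentage points were 0.737 for SP/KLF, 0.226 for PU.1, -0.335 for FOX, 0.00419 for HNF4 and -1.47 for the homeobox motif, each opposite to the matched value. Without replicate 1 or 2 T-box ranged from -0.102 to 0.294, FOX from -0.210 to 0.420 and NFY from -0.124 to -0.0247. In replicate 2 footprints 8 motifs were less frequent when limited to those found in both replicates and 8 without flanks, against 5. There T-box was -0.00332, homeobox -0.112 and POU -0.0553 in footprints of both, and homeobox -0.0268 and TEAD -0.0318 without flanks.

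In the comparison of libraries by list, 0 lists lay above and 0 below the central 95% of random lists with the number of peaks. With the promoter height alone 2 lay above and 0 below, and immediate early genes had 0.22. Over shared regions 4 lay above and 1 below, and with GC adjustment 3 above and 2 below.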

Other observations

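The odds ratios between peaks of a single library and the values of the promoters kept were computed after the data were seen, and the sequence copies of strong regions were counted as planned.

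Several other motifs also differed between distal peaks found in a single library. Within bins of GC content and height, the odds of a motif in peaks of replicate 2 alone over those of replicate 1 alone were 2.28 (95% interval 1.54 to 3.38) for MEF2, 2.05 (1.85 to 2.29) for the NEUROD-type E-box, 1.79 (1.35 to 2.38) for the POU octamer, 1.63 (1.05 to 2.53) for ROR, 1.49 (1.15 to 1.91) for the T-box motif, 1.33 (1.13 to 1.57) for the homeobox motif and 1.33 (1.03 to 1.70) for PU.1. They were 0.125 (0.106 to 0.147) for CTCF, 0.432 (0.292 to 0.637) for NR4A, 0.468 (0.314 to 0.698) for SP/KLF, 0.718 (0.580 to 0.890) for FOX, 0.371 (0.144 to 0.958) for NFI and 0.457 (0.212 to 0.986) for HNF4. For SOX the value was 1.02 (0.90 to 1.17), for RFX 0.925 (0.589 to 1.45) and for EGR 0.681 (0.328 to 1.41).

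Lists with at least 5 promoter peaks in replicate 1 were set against random lists matched on GC content and height by the number kept in replicate 2. Inhibitory neuron genes kept 9 of 12, with a mean of 8.72 in matched lists, astrocyte genes 10 of 12 (9.04), oligodendrocyte genes 7 of 9 (6.17), pan-neuronal genes 13 of 14 (13.2) and striatum genes 8 of 10 (7.87). All of the 14 lists examined except the excitatory neuron list lay within the central 95% of matched lists. Lists with fewer were not examined, among them mural genes, with 3 promoter peaks in replicate 1 and 0 in replicate 2, and choroid plexus genes, with 3 and 1.

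Several of the tallest distal peaks lie in repeated sequence. The tallest in replicate 1 was in an exon of Lars2, a mitochondrial leucine-tRNA ligase gene, at chromosome 9, 123461901 to 123462140, with heights of 30.4 and 18.5 and 77.3% of its 25-mers in more than 1 copy. The tallest in replicate 2 was at chromosome 3, 5860361 to 5860530, with 23.5 and 20.98, and all of its 25-mers were in more than 1 copy. Of the 60 strongest distal candidates 16 had 50% or more of their 25-mers in more than 1 copy.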
